A study of Homo sapiens with 6 samples.

How the data were processed

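Gene expression was measured on 6 one-colour Agilent human 4x44K microarrays hybridised with Cy3-labelled cRNA from MHCCLM3, an established human hepatocellular carcinoma cell line. By the sample titles, 3 arrays carried RNA from cells overexpressing ALDH2 (replicates 1, 2 and 3) and 3 carried RNA from cells overexpressing GFP (replicates 1, 2 and 4), and every array was taken as 1 sample of its group. The titles of GFP replicates 1 and 2 also carry a 2 in parentheses, whose meaning the labels do not give. These arrays share a slide, and whether they are repeat arrays is open: the SD across genes of their log2 difference was 0.23, against 0.17 to 0.18 between ALDH2 arrays. Per the labels, RNA integrity was checked on a Bioanalyzer and the RNA was amplified with a low-input one-colour labelling kit.

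Per the file headers, spot intensity was extracted from the scans with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed spatial trends within each array. Low signals were replaced by surrogate values, per the file headers. These processed intensity values still differed between arrays in their 75th percentile, so they were scaled here. The same deposited files give the raw mean intensity and the local background of each spot, and flags for control spots, outlier spots and spots well above background. The authors also deposited a series table of log2 values whose processing is not given in the sources used here. Set against the scanner values, each of its columns was linear in the log2 processed intensity of its own array (Pearson's r across probes between 0.999 and 1.000, slope between 0.987 and 1.02) and all 6 columns had a median of 6.59, so the table is on a log2 scale and aligned between arrays, with higher values for brighter spots. That deposited log2 table was used only as an alternative.

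From the processed intensities, control spots and spots flagged as outliers were left out, log2 values of repeated spots were averaged, and the 75th percentile of each array's log2 values was subtracted. A probe counted as well above background on an array when at least 50% of its spots carried that flag (share 0.5). No spot was saturated. Of 41000 non-control probes, 27294 were named by matching their transcript accession to RefSeq genes of GRCh38.p14, 2383 by current symbol, 454 by an older symbol, 803 kept the file's name and 10066 had no gene name. Each of the 19601 named genes was represented by its brightest probe over the 6 arrays. The 14762 genes well above background on all 3 arrays of at least 1 group were tested, and 4839 were not. Probe positions are those of the files, on hg19 per the file headers.

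The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the tested genes, and a gene is said to be called, higher or lower, where its adjusted p was below 0.05. Log2 folds are ALDH2 minus GFP, and ± after a log2 fold is the standard error of the fit on 3 against 3 arrays. Where a gene was not well above background on any array of a group, the change is given as a lower bound ("at least N-fold"): the bright group's mean against the dim group's mean, in which each dim array takes the higher of its own value and the lowest value of any probe well above background on it. Such a bound holds for the processed signal only. Before the data were examined, 33 gene lists and the rule for naming genes were fixed. ALDH2 comes first, then the 10 largest positive and the 10 largest negative log2 folds among called genes whose groups do not overlap, leaving out accession, LOC, open reading frame and KIAA or FLJ names and pseudogenes, and then up to 4 members of each list with the smallest adjusted p. Some members that this rule takes are not reported here. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether the members of a list move one way on balance and does not compare them with other genes. Adjusted p-values of lists are over the 33 lists.

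The fit was tested on simulated arrays with the means and spreads of 14754 real genes, 200 of them changed. For the comparison of ALDH2 with GFP it recovered 58.6% of genes changed by a log2 fold of 0.5 and 87.0% of those changed by 1, with a mean of 9.4 false calls among 155 calls over 5 simulations. The simulated noise was independent between genes, with 1 spread per gene for both groups and no slide effect. On the real arrays the median gene SD was 0.06 for ALDH2 and 0.09 for GFP, so these rates may not hold there. Alternatives were normexp background correction with quantile normalization (its offset of 50, added to each signal, shrinks the folds of dim probes), quantile normalization, median scaling, the deposited series table, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, slide as a random block, the replicate number as a block, limma-trend with robust moderation, no variance moderation, and leaving out each array. Leaving out both GFP arrays of lower detection and leaving out genes in more than 1 list were added after seeing the data. The number of arrays limits the precision, and nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Figures and checks used Python 3.11.15 with pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.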

Results

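MHCCLM3, a hepatocellular carcinoma line used as a model of metastatic liver cancer, was profiled after overexpression of ALDH2, the mitochondrial aldehyde dehydrogenase that oxidises acetaldehyde to acetate, and after overexpression of GFP as the control, to find the genes whose expression differs between them. There were 3 arrays per group. The share of the 41000 probes well above background was 73.4%, 72.1% and 73.8% on ALDH2 replicates 1, 2 and 3 and 73.1% on GFP replicate 1, and it was lower on GFP replicates 2 and 4, at 66.2% and 67.7%. The 75th percentile of the processed signal was 1099, 1141 and 1101 on the ALDH2 arrays and 1142, 1028 and 889 on GFP replicates 1, 2 and 4. The ALDH2 arrays lay on 1 slide, GFP replicates 1 and 2 on another and GFP replicate 4 on the third. The ALDH2 arrays were closer to one another than the GFP arrays were: the SD across genes of the log2 difference between 2 arrays was 0.17 to 0.18 within ALDH2, 0.23 to 0.30 within GFP and 0.26 to 0.34 between the groups. The first principal component held 48.4% of the variance and separated the groups, and the second, with 24.7%, set GFP replicate 4 apart from GFP replicates 1 and 2.

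The arrays carry a pair of ALDH2 probes, both in the same stretch of chromosome 12 (hg19, 112247448 to 112247507 and 112247691 to 112247750), and neither separated the groups. The brighter probe, A_23_P36745, had a log2 level relative to the array's 75th percentile of 3.04 ± 0.04 (SD, n = 3) on the ALDH2 arrays and 2.99 ± 0.06 (SD, n = 3) on the GFP arrays. The other, A_23_P36753, stood at 0.66 ± 0.01 (SD, n = 3) and 0.61 ± 0.08 (SD, n = 3). The log2 difference of the brighter probe was 0.05 with a 95% confidence interval from -0.07 to 0.18, and its exact permutation p was 0.3, where the smallest p that 3 arrays against 3 allow is 0.1. For the other probe the difference was 0.06, with an interval from -0.08 to 0.20 and an exact permutation p of 0.4. As listed, the sequence of A_23_P36753 (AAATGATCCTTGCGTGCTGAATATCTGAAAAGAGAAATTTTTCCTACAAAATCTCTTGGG) holds a stop codon in each of its 3 reading frames, so, if that is the strand of the transcript, it does not lie wholly within coding sequence. Its reverse complement holds a stop codon in 1 of 3 frames. The other probe, 184 bases further at higher coordinates, holds a stop codon in 1 of its 3 frames, which leaves its place open. The labels do not state which part of the ALDH2 transcript the construct carried, so the probes were not used to check the labels. Groups are named by their labels throughout.

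Against GFP, the arrays labelled ALDH2 had 572 genes higher and 681 genes lower among 14762 tested. Most changes were small, with a median absolute log2 fold of 0.39 among the called genes, and by the fitted fold 29 genes were at least 2-fold higher and 49 at least 2-fold lower. In 8 of the 29 the probe was well above background on no GFP array, so their changes have only bounds, which ran from at least 1.01-fold to at least 1.83-fold in 7 of them, and CACNA2D2, named after its values were seen, had no bound. The groups did not overlap in 5091 genes (34.5%), where exchangeable arrays give 10% on average. Genes are not independent and all ALDH2 arrays shared 1 slide, so this share cannot tell the group from the slide. Of the called genes with another tested probe, its log2 fold had the same sign in 174 of 193 higher genes and in 228 of 265 lower genes. Sign alone takes in probes that stayed level, such as the second TAF5L probe at 0.02. Fewer genes were matched in size. The other log2 fold, multiplied by 2, reached that of the probe used in 131 of the 193 and 163 of the 265. The counts depended on single arrays. Without ALDH2 replicate 1, 2 or 3 they were 145 higher and 211 lower, 90 and 155, and 190 and 242, and without GFP replicate 2 they were 211 and 292. They moved less without GFP replicate 1, to 495 and 472, or GFP replicate 4, to 592 and 754. With slide as a random block, 162 genes were higher and 242 lower, and since all ALDH2 arrays shared 1 slide, that slide and the group were not separable. Without both GFP arrays of lower detection, replicates 2 and 4, the counts were 115 and 150. With normexp background correction they were 258 and 312, with no filter on dim probes 231 and 426, and without variance moderation 264 and 407. The 2-fold counts moved too: with normexp they were 9 higher and 14 lower. The 29 genes at least 2-fold higher became 10, 6 and 19 without ALDH2 replicate 1, ALDH2 replicate 2 and GFP replicate 2, 11 with slide as a random block, 18 with no filter, 17 on probes well above background on all 6 arrays and 7 without variance moderation. Without ALDH2 replicate 3, GFP replicate 1 and GFP replicate 4 they were 21, 39 and 33.

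The 10 largest decreases among the genes taken by the naming rule had log2 folds from -2.31 to -1.73. LCP1, which encodes the actin-bundling protein L-plastin, fell by 1.89 on the log2 scale (SE 0.06, adjusted p = 0.000208) and was well above background on 2 of the 3 ALDH2 arrays. RASD1, a dexamethasone-induced Ras-like GTPase, fell by 1.79 (SE 0.06, adjusted p = 0.000208), and CYB5R2, a cytochrome b5 reductase, by 1.87 (SE 0.10, adjusted p = 0.00103). FAM50B fell by 1.73 (SE 0.09) from a log2 level of 0.53 ± 0.14 (SD, n = 3) to -1.20 ± 0.08 (SD, n = 3), and NECAB1, which encodes an EF-hand calcium-binding protein, by 2.18 (SE 0.14), though a second NECAB1 probe, well above background on 2 arrays, differed by 0.08. The non-coding RNA LINC00520, whose probe lies on chromosome 14 (hg19, 56247878 to 56247937), fell by 2.31 (SE 0.06, adjusted p = 0.000194). NECAB1, LINC00520 and EVI2B were each well above background on 1 of the 3 ALDH2 arrays. The dimmest decile of all named genes had a median log2 fold of -0.57, the direction of these decreases at low signal. MEIOC, a gene of meiosis, was not well above background on any ALDH2 array and was 4.11-fold lower by the fitted fold on the processed signal (adjusted p = 0.00426). Its bound, at least 4.11-fold, was no lower than that fit (log2 fold -2.04, SE 0.19), so it leaves no margin for error. TMEM204 fell by 2.10 (SE 0.28), a call that ended without ALDH2 replicate 2 or 3 (highest adjusted p 0.0567). SPANXA2-OT1, within the near-identical SPANX copies of chromosome X and so of uncertain origin, fell by 2.23 (SE 0.41), and EVI2B by 1.73 (SE 0.39). The call of EVI2B was lost when any 1 of the 6 arrays was left out (up to adjusted p = 0.124), and that of SPANXA2-OT1 when any array but GFP replicate 4 was (up to 0.0875). With slide as a random block both calls ended (highest adjusted p 0.158) at log2 folds of -1.75 and -2.16, and 8 of the 10 decreases stayed past the threshold. The sizes and ranking of these decreases differed with normexp. Its offset of 50 by itself shrinks the folds of dim probes, so the part of the background correction is not known. The log2 folds were then -0.51 for LINC00520, -0.42 for NECAB1, -0.39 for LCP1 and -0.93 for TMEM204. For MEIOC it was -0.43, smaller than its bound on the processed signal. SPANXA2-OT1 then had the lowest of the 10, at -1.72, and EVI2B, at -0.23, was not called (adjusted p = 0.155).

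Of the 10 largest increases among the genes taken by the naming rule, 7 were not well above background on every GFP array. ACOT12, a cytosolic acetyl-CoA thioesterase, ACTL9, an actin-like protein, the non-coding LINC00479 and APOC2, the apolipoprotein cofactor of lipoprotein lipase, were well above background on all 3 ALDH2 arrays and on none of the GFP arrays. They were at least 1.31-fold, 1.01-fold, 1.83-fold and 1.12-fold higher on the processed signal, with adjusted p between 0.00407 and 0.0349. HNF4G, a nuclear receptor, was at least 1.19-fold higher (adjusted p = 0.00911) on a probe well above background on no GFP array, while a second HNF4G probe, well above background on 1 ALDH2 and 1 GFP array, differed by -0.22. SEMA3G, a secreted semaphorin, and RASGEF1B, a guanine nucleotide exchange factor, rose by log2 folds of 1.79 ± 0.30 and 1.42 ± 0.25 and were well above background on 1 GFP array each. Well above background on all 6 arrays were EML2, a microtubule-associated protein (log2 fold 1.78 ± 0.33), WLS, the carrier for Wnt secretion (1.65 ± 0.22), and TAF5L, a subunit of histone acetyltransferase complexes (1.60 ± 0.26), though a second TAF5L probe differed by 0.02. Without ALDH2 replicate 1 or 2, 3 of the 10 increases stayed past the threshold, without ALDH2 replicate 3, 7, and without GFP replicate 2, 6. Without GFP replicate 1 or 4 all 10 did. Of the 10 decreases, 7 to 9 stayed without any 1 array. With slide as a random block 4 of the 10 stayed, ACOT12, ACTL9, WLS and HNF4G, and the highest adjusted p of the others was 0.0957, at log2 folds between 1.37 and 1.83. ACOT12 and ACTL9 kept their calls without each single array. They lost them with normexp, whose offset shrinks the folds of dim probes, at log2 folds of 0.29 and 0.16 (adjusted p = 0.0565 and 0.310). The calls of APOC2 and RASGEF1B also ended there, at 0.18 and 0.26 (adjusted p = 0.231 and 0.0723). SEMA3G and LINC00479 stayed called at 0.36 and 0.30. The folds of ACOT12 and LINC00479 were smaller there than their bounds, which are for the processed signal only. HNF4G was not among the genes tested with normexp, with quantile normalization or in the deposited series table.

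**Figure D1:**
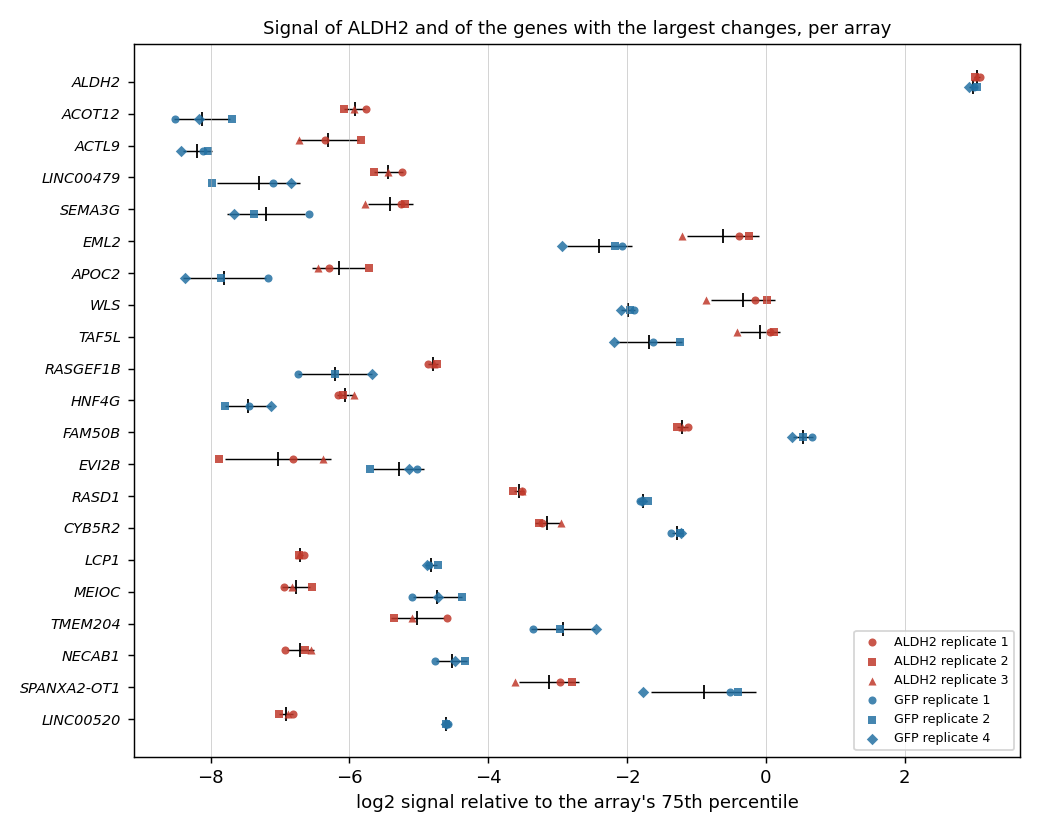
Log2 signal relative to the array's 75th percentile (x axis) for ALDH2 and the 20 genes with the largest changes among those the naming rule allows (y axis), with a symbol for each array, ALDH2 arrays in red and GFP arrays in blue, and black ticks and bars for group means ± SD (n = 3). The ALDH2 values overlap between the groups, while LINC00520, LCP1 and RASD1 show gaps far wider than the spread within either group.

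Inflammatory genes and targets of NF-kB were lower as a list in the arrays labelled ALDH2. Of 27 measured members, 9 fell, none rose and 18 were not called (14 fell and 1 rose adjusted over the list alone), and camera gave an adjusted p of 0.00269 (adjusted p = 0.183 with an estimated correlation). The members with the smallest adjusted p were TRAF1, an adaptor of TNF receptors, at -1.10 ± 0.07, BIRC3, an inhibitor of apoptosis, at -0.67 ± 0.05, LIF, a cytokine of the IL6 family, at -0.55 ± 0.05, and IL6 itself at -0.38 ± 0.05. Immediate early genes moved both ways, with 11 lower, 5 higher and 16 not called of 32 (16 lower and 6 higher adjusted over the list alone), and camera placed the list lower (adjusted p = 0.00537, and adjusted p = 0.183 with an estimated correlation). KLF2, a zinc finger transcription factor, fell by 0.96 (SE 0.05) and DUSP4, a phosphatase of MAP kinases, by 1.09 (SE 0.08), whereas NR4A1, an orphan nuclear receptor, and FOS rose by 0.79 ± 0.05 and 0.61 ± 0.05. TRAF1, BIRC3, LIF, KLF2, DUSP4, NR4A1 and FOS kept their calls without each single array, and IL6 lost its call without ALDH2 replicate 2 (adjusted p = 0.0624). Second probes of KLF2 and NR4A1 differed by 0.24 and -0.05, and with the mean of a gene's probes both calls ended, at -0.36 and 0.37 (adjusted p = 0.224 and 0.0989). A second LIF probe, well above background on 2 arrays, differed by 0.25, and FOS was at 0.35 with normexp. Of the 81 called list members taken by the naming rule, 21 kept their calls without each single array, 39 stayed past the threshold with slide as a random block, 51 with normexp and 73 with the mean of a gene's probes. The 42 that lost their calls with the slide block kept 96.7% to 103% of their log2 fold.

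The p53, ATF4 and CHOP, and autophagy and lysosome lists were also lower. Of 29 p53 targets, 5 fell, none rose and 24 were not called (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00537, and adjusted p = 0.183 with an estimated correlation). They included GADD45A, at -0.62 ± 0.08, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, at -0.31 ± 0.04. Of 35 targets of ATF4 and CHOP, 6 fell and 1 rose (10 and 2 adjusted over the list alone), with GDF15, a secreted stress cytokine, at -0.79 ± 0.07, SLC7A11, the cystine transporter, at -0.65 ± 0.07, ATF3 at -0.45 ± 0.05 and DDIT3, which encodes CHOP, at -0.55 ± 0.06. The ATF4 and CHOP list was at the margin, with a camera adjusted p of 0.0490 (adjusted p = 0.183 with an estimated correlation) that rose above 0.05 without ALDH2 replicate 1 (0.0546), GFP replicate 1 (0.0717) or GFP replicate 4 (0.0659), with no filter on dim probes (0.164) and on probes well above background on all 6 arrays (0.0632). Of 33 autophagy and lysosome genes, 2 fell, the sialidase NEU1 and the protease CTSD at -0.33 ± 0.06 and -0.25 ± 0.05, and 1 rose, CTSF at 0.27 ± 0.06 (2 and 1 adjusted over the list alone). Its camera adjusted p was 0.00815, and adjusted p = 0.183 with an estimated correlation. CTSD and CTSF lost their calls when any 1 of the 6 arrays was left out (up to adjusted p = 0.150), and NEU1 without ALDH2 replicate 1 or 2 or GFP replicate 1 or 2 (up to 0.104). GADD45A and ATF3 lost theirs without ALDH2 replicate 2 and CDKN1A without any 1 ALDH2 array (up to 0.0687). With normexp NEU1, CTSD, CTSF, CDKN1A and ATF3 were not called, at -0.36, -0.23, 0.31, -0.26 and -0.41 (adjusted p between 0.0555 and 0.184).

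Genes tied to invasion were lower as a list. Of 26 proteases and adhesion genes, 8 fell, none rose and 18 were not called (10 fell and 1 rose adjusted over the list alone), with a camera adjusted p of 0.00391 (adjusted p = 0.286 with an estimated correlation). Among them, ITGAV, the integrin alpha V chain, stood at -0.30 ± 0.04, PLAUR, the urokinase receptor, at -0.45 ± 0.08, and TIMP2, which inhibits metalloproteases, at -0.27 ± 0.05. Of 20 mesenchymal markers, 3 fell and none rose (6 and 1 adjusted over the list alone): SNAI2, the transcription factor Slug, at -0.71 ± 0.09, CDH2, which encodes N-cadherin, at -0.54 ± 0.08, and ZEB2 at -0.40 ± 0.06. A pair of further ZEB2 probes differed by 0.28 and 0.19, and with the mean of its probes the ZEB2 call ended, at -0.11 (adjusted p = 0.573), as did that of ITGAV, at -0.24 (0.111). The mesenchymal list's camera adjusted p was 0.0230 (adjusted p = 0.183 with an estimated correlation), and 0.0514 without GFP replicate 4 and 0.0533 with no filter on dim probes, where the TGF-beta list had the same value. Of 27 TGF-beta targets, 4 fell, namely INHBA at -0.60 ± 0.07, SNAI2, TGFBI at -0.35 ± 0.05 and KLF10 at -0.48 ± 0.08, and none rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0213, and adjusted p = 0.183 with an estimated correlation). With normexp INHBA, TGFBI, PLAUR and TIMP2 were not called, at -0.15, -0.35, -0.42 and -0.25 (adjusted p = 0.336, 0.0679, 0.0747 and 0.0985). Among 24 epithelial junction and keratin genes, 2 rose, CLDN7 at 0.68 ± 0.09 and DSP at 0.23 ± 0.05, and none fell (2 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.428). With normexp CLDN7 was at 0.44 and DSP was not called, at 0.05 (adjusted p = 0.829). Of the genes named in these lists, INHBA kept its call without each single array, and the others lost theirs without at least 1, ALDH2 replicate 2 among them for each gene (highest adjusted p over single arrays 0.167).

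The lists that were higher held few called members. Of 34 DNA replication genes, GINS1 and LIG1 rose, by 0.31 ± 0.06 and 0.37 ± 0.08, and none fell (2 and 0 adjusted over the list alone), while 27 had a positive log2 fold, and camera gave an adjusted p of 0.00537 (adjusted p = 0.183 with an estimated correlation). Of 15 aldehyde dehydrogenase family genes, 1 rose, the succinate semialdehyde dehydrogenase ALDH5A1 at 0.51 ± 0.06 (2 and 0 adjusted over the list alone), and 13 had a positive log2 fold (camera adjusted p = 0.00750, adjusted p = 0.183 with an estimated correlation, and 0.0520 with no filter on dim probes). Of 25 cholesterol synthesis genes, 3 rose, PMVK and INSIG1 among them, at 0.36 ± 0.05 and 0.33 ± 0.07, and none fell (3 rose and 2 fell adjusted over the list alone). The camera adjusted p of that list, 0.0471 (adjusted p = 0.399 with an estimated correlation), became 0.0505 without ALDH2 replicate 1, 0.106 without ALDH2 replicate 2, 0.0809 without GFP replicate 1 and 0.0641 with quantile normalization. All 5 genes named in these lists lost their calls without ALDH2 replicate 2, and 4 of them also without other arrays (highest adjusted p 0.147), and with normexp GINS1 was not called, at 0.24 (adjusted p = 0.163). Fry gave adjusted p between 0.00107 and 0.0434 for the 11 called lists, and no list had an adjusted p below 0.05 with an estimated correlation. Fry does not set the called lists apart, since it was also below 0.05 for uncalled ones. These were mitochondrial biogenesis (0.0143), fatty acid synthesis (0.0239), NRF2 and YAP targets (0.0246 each), fibroblast markers (0.0361) and fatty acid oxidation (0.0433). Without both GFP arrays of lower detection, the ATF4 and CHOP, TGF-beta, immediate early and autophagy lists were not called (adjusted p between 0.0594 and 0.0738). Their median log2 folds were then -0.07, -0.06, -0.20 and -0.08, against -0.05, -0.07, -0.21 and -0.10 on all arrays. When the 57 genes that belong to more than 1 list were left out, 7 of the 11 called lists stayed called. The ATF4 and CHOP (0.122), mesenchymal (0.0621), TGF-beta (0.0721) and cholesterol (0.0581) lists did not.

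Other lists were not called as a whole, and their counts adjusted over the list alone follow in parentheses, higher first. Of 30 AMPK subunits and partners, 2 rose and 2 fell: the gamma subunit genes went apart, PRKAG1 at 1.11 ± 0.20 and PRKAG2 at -0.45 ± 0.06, with FLCN at -0.37 ± 0.05 and SREBF1 at 0.34 ± 0.07 (2 and 2). With slide as a random block the PRKAG1 call ended at a log2 fold of 1.10 (adjusted p = 0.0934). Further FLCN probes differed by -0.17 and 0.20, and with the mean of its probes the FLCN call ended, at -0.11 (adjusted p = 0.389). Of 38 NRF2 targets and antioxidant genes, 1 rose, HMOX1 at 0.81 ± 0.12, and 4 fell, among them ABCC3 at -0.54 ± 0.07 (1 and 5). Of 24 YAP and TEAD targets, 3 rose, DLC1 at 0.81 ± 0.07 among them, and 5 fell, with ANKRD1 at -0.90 ± 0.09 (3 and 7). Of 35 interferon response genes, 1 rose, IFITM1 at 0.72 ± 0.06, and 5 fell, IFI44 at -0.66 ± 0.05 and IRF1 at -0.51 ± 0.06 among them (1 and 7). Of 16 WNT and beta-catenin targets, 3 rose and 2 fell, with DKK1, a secreted Wnt inhibitor, at -0.71 ± 0.05 (3 and 2). Among 20 hepatocyte function genes, CPS1 and ASS1 of the urea cycle rose by 0.53 ± 0.06 and 0.48 ± 0.09, and CYP3A4 and F2 fell by 0.78 (SE 0.10) and 0.39 (SE 0.07) on the log2 scale (2 and 2). With normexp CYP3A4, F2 and FLCN were not called, at -0.27, -0.13 and -0.30 (adjusted p = 0.0582, 0.409 and 0.122). Among 31 genes of mitochondrial biogenesis and the tricarboxylic acid cycle, 2 rose, IDH2 at 0.69 ± 0.06 and SUCLG2 at 0.37 ± 0.06, and none fell (2 and 0), and SUCLG2 was not called with normexp, at 0.31 (adjusted p = 0.0709). DLC1, ANKRD1, IFITM1, IFI44, IRF1, DKK1, CPS1 and IDH2 kept their calls without each single array, and the other genes named here lost theirs without at least 1, ALDH2 replicate 2 among them for each gene (highest adjusted p 0.118). Camera's adjusted p for these 7 lists lay between 0.0625 and 0.705.

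The remaining lists held few calls. Among 17 genes of alcohol and aldehyde metabolism other than ALDH, GSTA4 rose and AOX1 fell, at 0.48 ± 0.08 and -0.61 ± 0.08 (1 and 1). Of 12 hepatic progenitor and stem cell markers, POU5F1, which has near-identical pseudogenes, rose and CD44 fell, at 0.84 ± 0.15 and -0.19 ± 0.04 (1 and 2). Single genes changed among 28 endoplasmic reticulum chaperones (DERL3 at 0.23 ± 0.05), 21 heat shock genes (HSPB8 at -0.23 ± 0.05), 52 nuclear oxidative phosphorylation genes (ATP5F1D at 0.21 ± 0.04) and 34 mitotic genes (DLGAP5 at 0.22 ± 0.05), with 0 and 0 adjusted over each of these lists alone. Of 25 hypoxia targets, ADM and KDM3A fell, at -0.37 ± 0.05 and -0.21 ± 0.05 (6 and 6). Of 25 fatty acid and triglyceride synthesis genes, FADS2 and SREBF1 rose and DGAT1 fell, at 0.22 ± 0.04, 0.34 ± 0.07 and -0.30 ± 0.06 (6 and 3). Of 22 fatty acid oxidation genes and PPARA targets, PDK4 and HADH rose, at 0.37 ± 0.07 and 0.25 ± 0.05 (2 and 1). GSTA4, AOX1, POU5F1 and the other called genes named here each lost their calls without at least 1 single array (highest adjusted p 0.172), ADM without ALDH2 replicate 1 or 3 and the others without ALDH2 replicate 2 among others. With normexp CD44, DERL3, HSPB8, ATP5F1D, DLGAP5, KDM3A, FADS2, PDK4 and HADH were not called, at log2 folds between -0.29 and 0.28 (adjusted p between 0.0656 and 0.453). By limma, none of 26 glycolysis genes or 55 cytosolic ribosomal protein genes was called, and 0 and 0 were adjusted over either list alone, with 4 glycolysis genes higher and 2 lower and 0 and 4 ribosomal genes at an unadjusted p under 0.05.

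Markers of other cell types were also measured. Of 12 fibroblast and stellate cell markers, CYGB, not well above background on any GFP array, was at least 1.08-fold higher (adjusted p = 0.0219), and PDGFRB rose, at 0.46 ± 0.08 (3 and 1 adjusted over the list alone). Of 13 leukocyte markers, 2 rose, MARCO at 0.45 ± 0.08 among them, and CD68 fell, at -0.61 ± 0.07 (2 and 1). Of 10 endothelial markers, TEK, well above background on 1 GFP array, rose, at 0.78 ± 0.14 (1 and 1). The 1 lower over the list alone, STAB1, was not called over all genes (adjusted p = 0.0518), was well above background on no ALDH2 array, with a bound of at least 2.55-fold lower on the processed signal, and had a log2 fold of -0.26 with normexp. With normexp CYGB, PDGFRB and TEK were not called, at 0.03, 0.31 and 0.11 (adjusted p = 0.893, 0.108 and 0.564), and the fold of CYGB was smaller than its bound on the processed signal. CD68 kept its call without each single array, and CYGB, PDGFRB, MARCO and TEK lost theirs without ALDH2 replicate 2 and other arrays (highest adjusted p 0.108). None of these lists was called (adjusted p = 0.114, 0.863 and 0.331). Median, mean and camera's direction differed in sign for NRF2 targets, heat shock genes, AMPK genes, hypoxia targets, leukocyte markers and endothelial markers, with medians between -0.04 and 0.11.

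**Figure D2:**
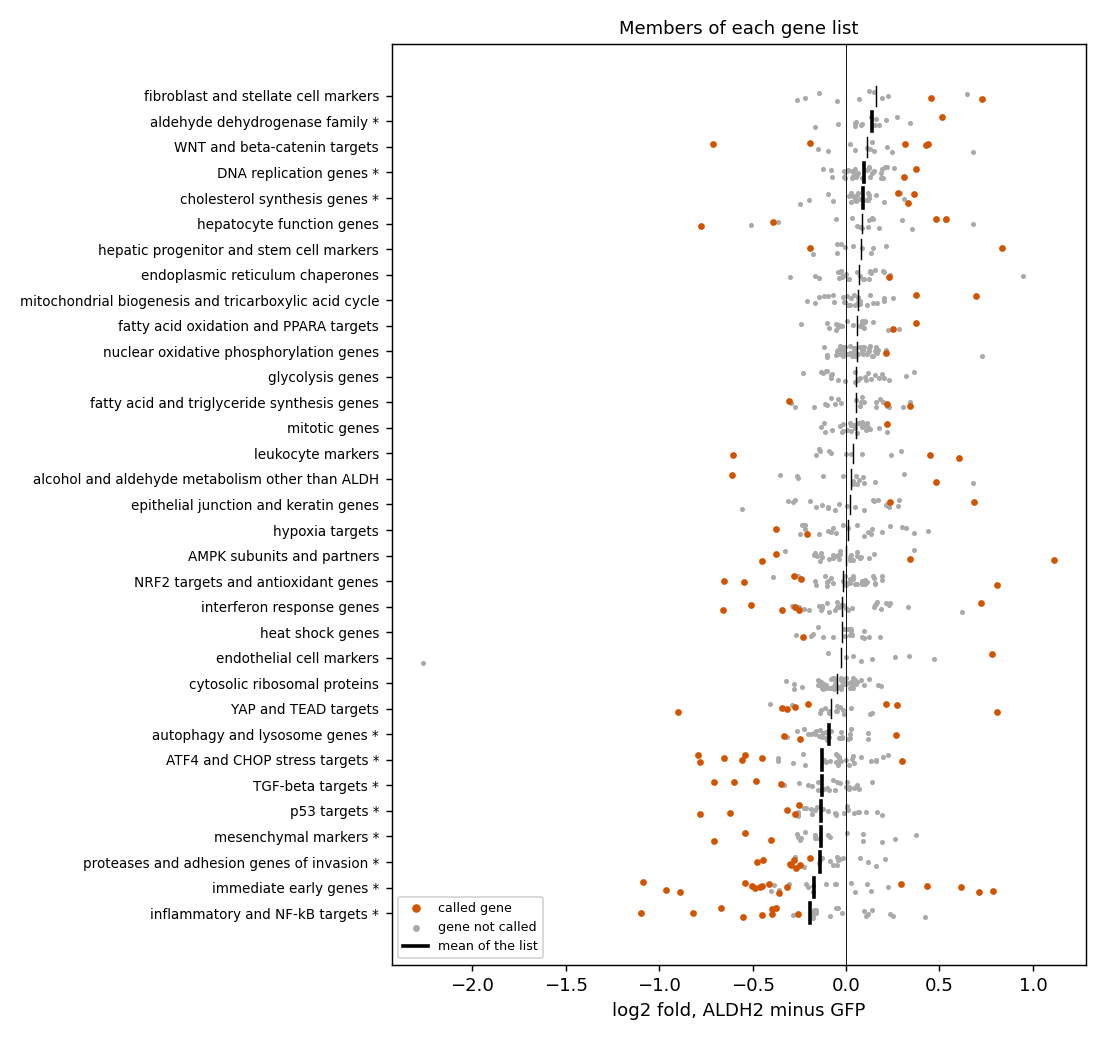
Log2 fold of ALDH2 minus GFP (x axis) for each measured member (points) of the 33 gene lists (y axis, ordered by mean), with called genes in orange, other genes in grey and a black line at the list's mean, thick and with an asterisk by the name where camera's adjusted p was below 0.05. The called lists are displaced by small amounts, with a mean of -0.19 for inflammatory and NF-kB targets at the bottom and 0.14 for the aldehyde dehydrogenase family near the top.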

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

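All tests in this part were chosen after the results were seen. Among 5872 tested probes without a gene name, which enter no comparison above, 103 were higher and 70 were lower with ALDH2 in a limma fit over all tested probes, 8 and 9 of them by at least 2-fold. They are given as signal in data that no gene-level result uses, and the share called, 2.95%, was lower than the 8.49% among named genes in their own fit.

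The ALDH2 probes were level between the groups although the labels name ALDH2 as the overexpressed gene. On whether 1 array stood under the label of the other group, 0 of the 6 arrays lay closest to an array of the other group. This cannot decide it, because arrays of the same slide lay closest together and no slide held both groups. GFP replicate 4, alone on its slide, differed from GFP replicate 2 by an SD of 0.29 and from ALDH2 replicate 3 by 0.33. A complete exchange of the labels would also look the same. A candidate explanation is probes outside the coding sequence: as listed, 3 of the 3 reading frames of the probe at lower coordinates hold a stop codon. In the reverse complement of that probe 1 of 3 frames does, so this rests on the listed strand. For the brighter probe, at higher coordinates, 1 of 3 frames as listed holds a stop codon, so its sequence leaves this open. Whether the construct raised ALDH2 stays open, because the labels do not state what the construct carried.

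Of the 29 genes at least 2-fold higher by the fitted fold, 16 were well above background on all 6 arrays, and in these ALDH2 replicate 3 stood below the other ALDH2 arrays, by a median log2 value of -0.31, against 0.0004 over all genes, and below both in 10 of the 16. A trend on probe GC content or array position that all genes share is argued against as the whole cause. After removing each trend, 15 and 16 of the 16 genes stayed at least 2-fold higher. The trends removed were small, with EML2 going from 1.78 to 1.76 and 1.82. These tests therefore cannot decide on an artifact of single probes or spots. A signal of 1 probe is argued against for GAMT, RHOV and RALGDS, 3 genes whose second probe moved by 0.95, 1.16 and 1.30. It may account for TAF5L and PIP5K1A, the 2 genes whose second probe stayed level at 0.02 and 0.08, where a change of 1 transcript form is equally open, and for the 11 genes without another tested probe, PRKAG1, WLS and EML2 among them, the tables hold no value that decides. An effect of ALDH2 stays open and untested, as does the slide that all ALDH2 arrays shared.

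The other 13 genes at least 2-fold higher had a probe not well above background on every GFP array, and 8 of these probes were well above background on none of them. A shift of all dim probes could contribute and cannot be told apart here, because 0 of the 13 were well above background on at least 2 GFP arrays, so that no fold among them is measured well enough to decide. The dimmest decile of the named genes had a median log2 fold of -0.57, the direction opposite to these genes and the same as that of LINC00520, NECAB1, MEIOC, LCP1 and EVI2B, each well above background on at most 2 of the 3 ALDH2 arrays. The lower detection on GFP replicates 2 and 4 could contribute and cannot be told apart from the group here, because the test rests on 1 array: GFP replicate 1, with detection like that of the ALDH2 arrays, lay nearer to the ALDH2 mean in 1 of the 13 genes. An effect of ALDH2 stays open and untested.

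Of the 10 splits of the 6 arrays into equal groups, 1, the real one, gave 1253 called genes and 78 called at least 2-fold, and the highest of the others gave 0 and 0. For gene lists the real split gave 11 and the highest other 3. With 10 splits no share below 0.05 is possible. The other splits mix ALDH2 and GFP arrays, so any group or slide difference widens their residual spread. The real split also follows the slide of the ALDH2 arrays, so the contrast cannot tell group from slide.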

How the results depend on the processing

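Leaving out both GFP arrays of lower detection and leaving out genes shared between lists were chosen after seeing the data; the other settings were fixed before. Cause was not tested unless stated. Genes higher and lower (572 and 681) became 258 and 312 with normexp and quantile normalization, 231 and 426 with no filter on dim probes (35.2% of calls higher against 45.7%), 162 and 242 with slide as a random block (consensus correlation 0.262), 264 and 407 without variance moderation, and 115 and 150 without both GFP arrays of lower detection, where the lone GFP array is assumed to vary like the others. Leaving out single arrays gave 90 to 592 and 155 to 754, with fewer arrays. Genes at least 2-fold higher (29) became 9 with normexp, 18 with no filter, 17 on probes well above background on all 6 arrays (dim genes are not tested there), 11 with the slide block, 7 without moderation and 6 to 39 without single arrays. Genes at least 2-fold lower (49) became 14 with normexp and 33 to 55 without single arrays. Quantile normalization, median scaling, the deposited series table, the mean of a gene's probes and limma-trend moved none of these counts by over 1.5 times. The 11 called lists became 0 with an estimated correlation, 7 without shared genes and 8 to 13 in all other settings. The estimate lay above the preset 0.01 in some called lists, such as invasion (0.09) and cholesterol (0.11). In the mesenchymal and p53 lists it lay below, at -0.05 and -0.02. Camera's unadjusted p still rose there, from 0.0063 to 0.041 and from 0.00077 to 0.019, so a higher correlation was not what raised it in these lists. The ALDH2 probe stayed between 0.02 and 0.08 and uncalled. No called list changed the sign of its median and no called gene taken by the naming rule changed sign, though medians near 0 of uncalled lists did. Of the 1253 called genes, 4 had the opposite sign with normexp, 6 with the mean of a gene's probes and 1 in the deposited series table. Without variance moderation the mesenchymal (0.0549), ATF4 and CHOP (0.0787) and cholesterol (0.0539) lists were not called, and in the deposited series table the cholesterol list was not (0.0652). Without both GFP arrays of lower detection 4 of the 10 largest increases and 7 of the 10 decreases stayed called, with fewer arrays in the fit. The lost increases had log2 folds of 1.02 (APOC2, from 1.65), 1.17 (SEMA3G, from 1.79) and 1.47 to 1.81 (EML2, TAF5L, WLS and ACTL9), and the lost decreases of -1.66 (TMEM204, from -2.10), -2.00 (EVI2B) and -2.61 (SPANXA2-OT1). HNF4G was not tested with normexp, quantile normalization or the deposited series table. Uncalled lists that were called in some settings were nuclear oxidative phosphorylation (4 settings), mitotic genes (4) and ribosomal proteins (3).

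Arrays with the replicate numbers shared by the groups, 1 and 2, showed no common deviation, with correlations of deviations of -0.01 and 0.02. Unmatched arrays were not compared, so whether these numbers pair the arrays stays open. With the replicate block, limma called 0 genes higher and 0 lower (0 and 0 at least 2-fold), with 3418 at an unadjusted p under 0.05 against 4017, because 1 residual degree of freedom remained. Signal near background limits the 13 dim genes that were at least 2-fold higher.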

Other observations

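The families here were chosen by symbol after the values were seen, and 8 were tested with camera, so the tests describe these arrays. All 4 tested genes with a SPANX symbol fell on their brightest probes. They were SPANXA1 at -1.19 ± 0.12, SPANXB1 at -1.21 ± 0.11 and SPANXD at -1.06 ± 0.08, cancer-testis genes of chromosome X, and the non-coding RNA SPANXA2-OT1 at -2.23 ± 0.41. Camera on all 4 gave an adjusted p of 3.1e-05 (adjusted p = 0.0493 with an estimated correlation). The copies are nearly identical, so the probes are not independent measurements and the SPANXA2-OT1 signal is of uncertain origin. Of 21 genes of other cancer-testis families, PAGE1 rose, at 0.92 ± 0.07, none fell, and the set was not called (adjusted p = 0.292). SPANXA1, SPANXB1, SPANXD and PAGE1 kept their calls without each single array, and with normexp PAGE1 was at 0.41.

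Of 16 TNF receptor superfamily genes, 5 fell and 1 rose (adjusted p = 0.00308, and adjusted p = 0.0673 with an estimated correlation), with TNFRSF9 at -1.26 ± 0.10, TNFRSF14 at -0.70 ± 0.06, TNFRSF10C at -0.56 ± 0.06 and TNFRSF8 at 0.71 ± 0.12. With normexp TNFRSF9 was at -0.33, and TNFRSF10C and TNFRSF8 were not called, at -0.27 and 0.27 (adjusted p = 0.0647 and 0.0844). With the mean of its probes TNFRSF10C was not called, at -0.14 (adjusted p = 0.615), and TNFRSF8 was not called without any 1 ALDH2 array (up to 0.0977). Of 417 genes named ZNF, most of which encode zinc finger proteins, 22 fell and 6 rose, and the median log2 fold was -0.07 (adjusted p = 0.00102, and adjusted p = 0.00958 with an estimated correlation). The medians of the SPANX, TNF receptor and ZNF sets were negative in each of the 18 other settings. Of 16 semaphorins, SEMA3G and SEMA4C rose, SEMA4C at 0.86 ± 0.15, SEMA6A, not well above background on any GFP array, was at least 1.04-fold higher, and SEMA3C fell, at -0.66 ± 0.06 (adjusted p = 0.0415, and adjusted p = 0.209 with an estimated correlation). A set of 17 genes was taken by symbols that begin with APO and a letter from A to F, L, M or O. That pattern also takes APOBEC symbols, so the set does not stand for apolipoproteins alone. In it APOC1 rose, at 0.66 ± 0.12, and APOC2 was at least 1.12-fold higher. Camera gave the set an adjusted p of 0.0255 (adjusted p = 0.315 with an estimated correlation), and its median was -0.01 with no filter on dim probes. With normexp SEMA6A and APOC1 were not called, at 0.14 and 0.27 (adjusted p = 0.410 and 0.0788). SEMA3C kept its call without each single array, while SEMA4C, SEMA6A and APOC1 lost theirs without any 1 ALDH2 array, among others (up to 0.132). Of 14 serpins, 1 rose and 2 fell, and of 20 HLA genes 1 rose, and neither set was called (adjusted p = 0.845 and 0.209).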
